A study of Arabidopsis thaliana with 6 samples.

How the data were processed

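RNA from shoots of dark-grown seedlings was extracted with a column kit, amplified with a whole-transcriptome kit and labelled with biotin, per the labels' protocols. The platform annotation supplied with the table is that of the Affymetrix ATH1 design. The values used are those of the series' deposited value table, with 22810 probe sets on 6 arrays, and each was taken as a log2 expression value as deposited by the authors. RMA, PLIER and MAS5 are named per the submitters' processing notes, and which of them made this table is not given in the sources used here. The log base is read from the values, which run from 0.63 to 12.98: as natural logs they would exceed the range of a 16-bit scanner. Background correction, filters and detection calls are not given in the sources used here, so a probe set near the array medians of 2.15 to 2.24 cannot be called expressed or not, and large log2 changes rest in part on readings at that level. The medians of the 6 arrays differed by less than 0.1, so the deposited values were not normalized again.

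Control probe sets (64) were left out of the comparison, leaving 22746. The platform annotation gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8730, which are unnamed here. Of the single-gene probe sets, 13436 were matched to current RefSeq genes (assembly TAIR10.1) by gene identifier, 48 by locus tag and 18 to the mitochondrial genome by symbol, and 11 kept the annotation's symbol, for 13355 genes in all. No coordinates are given, since no genome build is named by the files.

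Flight and ground arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates, 3 arrays against 3). P-values were adjusted with the Benjamini-Hochberg method over all probe sets tested, and probe sets with an adjusted p under 0.05 were called. SE are limma's moderated standard errors, and ± values are SD over 3 arrays. Gene lists were tested with camera (preset inter-gene correlation of 0.01) on 1 probe set per gene, that with the highest mean over all arrays, with all genes so represented as background and adjustment over the lists. Of 34 lists, 14 had fewer than 3 measured members and were not tested. These were cellulose synthesis (1), lignin and phenylpropanoid synthesis (2), arabinogalactan and fasciclin-like proteins (0), antioxidant enzymes (2), salicylic acid (1), chlorophyll synthesis (2), storage lipid mobilisation (2), root markers (2), vascular markers (0), phosphate starvation (0), gravitropism and phototropism (1), circadian clock (1), DNA damage (0) and glucosinolate synthesis (2). Of their members, COB (AT5G60920, log2 change 1.53) and HCT (AT5G48930, 0.74) passed the threshold. A list of cytosolic ribosomal proteins was not run, because the tables used here give no gene descriptions.

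The genes named were chosen by a rule fixed before the data were examined, as were the lists, tests and most alternatives. They are the 12 largest log2 changes in each direction among single-gene probe sets that passed the threshold with groups that did not overlap, 1 probe set per gene, and up to 4 members with the largest absolute change from each list that passed camera and from the cytoskeleton list. If fewer than 12 had passed in a direction, the next by smallest p would have filled the number, reported as values only; this was not needed. Lists that did not pass were to be described by count and median only, and single genes named from them are marked as chosen later.

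The limma procedure was tested on simulated values with the means and spreads of these 22746 probe sets. Of 100 probe sets changed by a log2 difference of 1, 49% were recovered, and of 100 changed by 2, 87% were, with 9 false calls. The simulated noise was independent between probe sets, with the same spread in both groups. These rates therefore need not hold for real arrays whose probe sets vary together. Alternatives were quantile normalization, median centring, leaving out dim probe sets, a trended and robust variance prior, array weights, the replicate number as a block, each array left out in turn, other thresholds, a plain equal-variance test, camera with an estimated correlation, fry and the mean of all probe sets of a gene. Alternatives added after the data were seen were centring on hybridization spike-ins, the mean of the 3 seed storage genes as a covariate, and flight replicates 2 and 3 against ground replicate 2 only. No arrays were identical, with Pearson correlations between arrays from 0.895 to 0.982 across probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.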

Results

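Transcript levels were measured on Affymetrix ATH1-type arrays in shoots of dark-grown Arabidopsis thaliana seedlings of the Landsberg accession, raised in canister hardware built for spaceflight. The labels assign 3 arrays to spaceflight and 3 arrays to a ground control, and in both groups they carry the replicate numbers 2, 3 and 4. The sample titles also hold a letter that is not explained, f for every flight array and h for every ground array. Whatever it stands for cannot be told apart from the group. The series title names the plant cytoskeleton in microgravity as the subject, so the comparison asks which transcripts differed between flown and ground seedlings, tubulin and actin genes among them. Array medians lay between 2.15 and 2.24 on the log2 scale, and 22746 probe sets were tested. The labels do not say whether the 3 arrays of a group came from separate dishes, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

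Seedlings grown in flight had higher transcript levels of the tubulin genes TUB1 and TUB6 and the expansin genes EXPA4, EXPA8 and EXPA9 than ground seedlings. They had lower levels of the late embryogenesis abundant (LEA) genes LEA18, AtLEA4-1, LEA4-5 and M10 and of the dehydrin genes LTI30 and COR47. In total 939 probe sets were higher and 413 lower in flight at an adjusted p under 0.05 in limma, and 658 and 314 of them changed by a log2 difference of at least 1. Among probe sets of a single named gene, 466 were higher and 205 lower. All 1352 called probe sets had groups that did not overlap. Over all probe sets tested, 5915 had groups that did not overlap, which is 26.0% where chance gives 10%. Every array weighed on these counts: 309 probe sets were higher and 142 lower without flight replicate 2, 188 and 83 without flight replicate 3, 312 and 129 without flight replicate 4, 1124 and 782 without ground replicate 2, 621 and 414 without ground replicate 3, and 526 and 270 without ground replicate 4. Centring each array on its hybridization spike-ins, a scaling chosen after the data were seen, gave 470 higher and 363 lower probe sets (the spike-in mean was 9.61 in ground replicate 4 and 10.13 to 10.20 on the other 5 arrays), and the 3 arrays with low seed storage values, flight replicates 2 and 3 and ground replicate 2, gave 346 and 287.

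LEA18 (AT2G35300), of a gene family whose products accumulate in maturing seeds and in tissue short of water, had a mean of 3.59 ± 2.86 in flight and 9.93 ± 1.39 on the ground (log2, SD, n = 3), a log2 change of -6.34 (SE 1.38) with an adjusted p of 0.0435 from limma. Flight replicate 4 read 6.79, against 2.64 and 1.32 in flight replicates 2 and 3. AtLEA4-1 (AT1G32560) changed by -5.83 (SE 0.85), with 5.38 in flight replicate 4 and 2.93 and 2.54 in flight replicates 2 and 3, LEA4-5 (AT5G06760) by -4.61 (SE 0.72) and the LEA gene M10 (AT2G41280) by -5.01 (SE 0.95). The dehydrin gene LTI30 (AT3G50970) changed by -4.67 (SE 0.45), from 7.19 ± 0.76 on the ground to 2.52 ± 0.66 in flight. PUB19 (AT1G60190), which encodes a U-box ubiquitin ligase, changed by -3.58. The other 6 of the 12 largest falls, which carry no symbol here and were not assigned to a family, were AT3G15670 (-6.05), AT2G23110 (-5.16), AT3G02480 (-4.99), AT5G42290 (-4.75), AT5G50360 (-4.33) and AT1G24600 (-3.52). Of these 12 genes, 3 to 12 passed the threshold when a single array was left out, with the fewest, 3, without flight replicate 3, then 4 without flight replicate 2, 7 without ground replicate 3, 8 without flight replicate 4 and 8 without ground replicate 4. With a trended and robust variance prior 7 of the 12 passed, with LEA18 at an adjusted p of 0.153 and M10 at 0.104, and with array weights 10 passed, with LEA18 at 0.0704. Quantile normalization passed 11. The seed storage mean as a covariate, chosen after the data were seen, passed 9, with changes of -4.99 to -3.14 over the 12 and of -4.54 in LEA18, -3.997 in AT3G15670 and -3.59 in PUB19, the 3 that did not pass.

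The arrays within a group differed in seed transcripts. PAP85 (AT3G22640), a vicilin-like seed storage protein gene, stood at 10.91 and 10.57 in ground replicates 3 and 4, at 7.38 in flight replicate 4, and at 1.90, 1.30 and 1.54 in flight replicates 2 and 3 and ground replicate 2. AT3G01570, an oleosin gene of the fixed seed storage list, stood at 8.06 and 8.59 in ground replicates 3 and 4, at 3.30 in flight replicate 4 and at 1.32, 1.21 and 1.50 on the other arrays in that order. OLEO3 (AT5G51210) of the same list stood at 6.35 and 6.43 in ground replicates 3 and 4 and at 2.31 in ground replicate 2. It read 4.15, 2.93 and 4.18 in flight replicates 2, 3 and 4, so it did not set flight replicate 4 apart from flight replicate 2. ICL (AT3G21720), of the untested storage lipid mobilisation list, was named after its values were seen. It read 9.26 and 10.92 in ground replicates 3 and 4, 4.91 in ground replicate 2, and 5.02, 4.74 and 5.9 in flight replicates 2, 3 and 4. Its log2 change was -3.14 (limma adjusted p 0.249), and that of SDP1 in the same list was -0.17 (0.832). The seed storage list had 3 measured members, of which 0 passed the test, with a median log2 change of -4.11 and a camera adjusted p of 0.183. Its median was -6.38 without ground replicate 2 (adjusted p 0.000405), -2.53 without ground replicate 3 (0.392) and -2.70 without ground replicate 4 (0.432), and its adjusted p ran from 0.000405 to 0.973 over the alternatives. The rule for named genes required every ground array, ground replicate 2 included, to lie above every flight array, and LEA18 read 8.34 there. Flight replicate 4 had a PAP85 value between those of the other arrays. It had the highest flight values of LEA18, AtLEA4-1, LEA4-5, AT3G15670, AT3G02480, AT5G42290, AT2G23110 and AT5G50360. It did not for M10, at 3.54, 3.20 and 3.47 in flight replicates 2, 3 and 4, nor for LTI30, at 3.18, 2.51 and 1.87, PUB19 or AT1G24600.

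**Figure D1:**
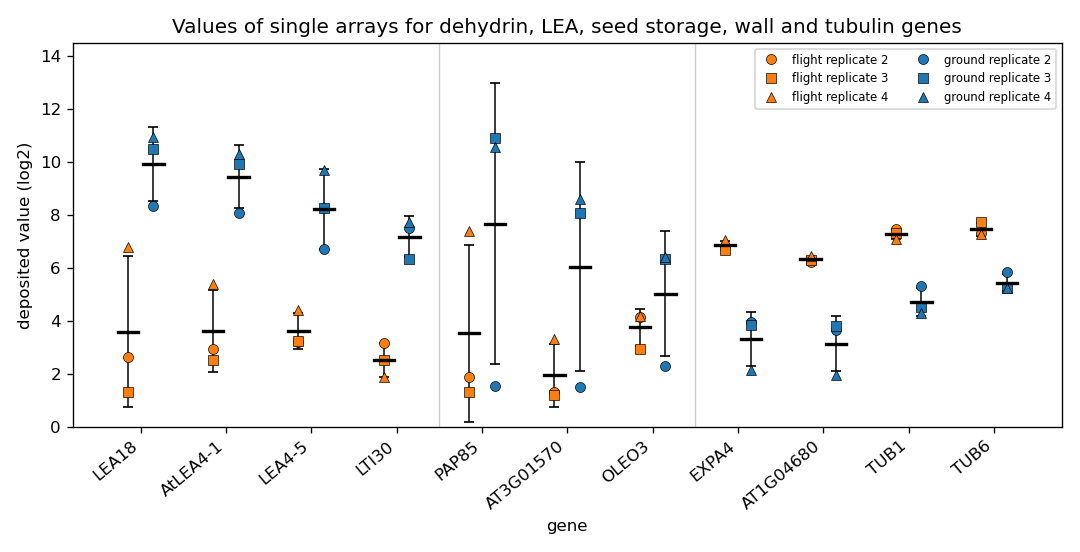
Deposited log2 values of 11 genes, with 1 point per array, a horizontal bar for each group mean and whiskers of 1 SD (n = 3 per group). LEA18, AtLEA4-1, LEA4-5 and LTI30 were higher on all 3 ground arrays than on any flight array, PAP85, AT3G01570 and OLEO3 were low in ground replicate 2, and the wall and tubulin genes on the right were higher on all 3 flight arrays.

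The largest rise was in AT3G45160, with a log2 change of 4.63 (SE 0.37), from 1.91 ± 0.66 on the ground to 6.53 ± 0.46 in flight (log2, SD, n = 3). EXPA4 (AT2G39700), an expansin that loosens cell walls, rose by 3.54 (SE 0.46), and the pectate lyase-like gene AT1G04680 rose by 3.18 (SE 0.46). AT5G45670 rose by 3.57 and AT2G23540 by 3.18, and both encode GDSL-type esterases or lipases. AT2G10940 rose by 3.79 (SE 0.26), from 6.17 ± 0.54 to 9.96 ± 0.09, and DRT100 (AT3G12610), a leucine-rich repeat protein gene, by 3.21. The remaining rises among the 12 largest were AT4G38080 (3.76), AT2G22510 (3.31), AT1G28400 (3.30), AT5G22580 (3.26) and AT2G47500 (3.15). All 12 passed the threshold when any 1 ground array was left out, and 10, 8 and 10 of them did without flight replicates 2, 3 and 4.

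Of the gene lists fixed beforehand, 20 had at least 3 measured members, and 8 of these shifted in flight in limma's camera test with a preset inter-gene correlation. None of the 20 passed with an estimated correlation (0 of 20, lowest adjusted p 0.252). Calls of single members are followed below over 8 alternatives that kept all 6 arrays, of which spike-in centring and the seed storage covariate were chosen after the data were seen, and over 6 that left out 1 array. On flight replicates 2 and 3 against ground replicate 2, 14 of the 27 called members of the 8 lists passed. The pectin list rose (8 measured, adjusted p 4.20e-05): 5 members were higher and 0 lower, also 5 when adjusted over the list alone, with a median log2 change of 2.02. All 5 risers are pectate lyase-like genes, which cut demethylated pectin, among them AT4G24780 (2.68), AT3G07010 (2.16) and AT3G53190 (2.13), and all 5 passed in 8 of 8 alternatives with all arrays and in 3 to 6 of 6 with 1 array left out. With an estimated correlation the adjusted p was 0.252. The list of expansins and xyloglucan endotransglucosylases rose (21 measured, adjusted p 0.000213), with 6 members higher and 0 lower, 8 when adjusted over the list alone, and a median of 0.32. That median was 0.087 without ground replicate 4, 0.17 after spike-in centring, 0.14 with the seed storage covariate, 0.17 on flight replicates 2 and 3 against ground replicate 2 and 1.76 once dim probe sets were left out. EXPA8 (AT2G40610) rose by 2.97 and EXPA9 (AT5G02260) by 2.60, while XTH19 (AT4G30290) had a log2 change of 1.95 with an adjusted p of 0.0814. The other called members, named after their values were seen, were XTH32 (1.90), EXPB3 (1.76) and XTH16 (0.97). EXPA8, EXPA9 and XTH32 passed in 8 of 8 alternatives with all arrays and in 6 of 6 with 1 left out, and EXPA4 in 8 of 8 and, missing without flight replicate 3, in 5 of 6. EXPB3 passed in 7 of 8, missing with the seed storage covariate, and in 3 of 6, missing without flight replicates 3 and 4 and ground replicate 4 in turn. XTH16 passed in 5 of 7, missing with spike-in centring and the seed storage covariate, and in 3 of 6, missing when any 1 flight array was left out. With an estimated correlation this list had an adjusted p of 0.390.

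The cytoskeleton list rose (10 measured, camera adjusted p 8.38e-06), with 4 members higher, 0 lower and a median of 0.89. All 4 were tubulin genes: TUB1 (AT1G75780) rose by 2.58 (SE 0.27), TUB6 (AT5G12250) by 2.01 (SE 0.22), TUB7 (AT2G29550) by 1.36 (SE 0.29) and the alpha-tubulin gene TUA6 (AT4G14960) by 1.30 (SE 0.18). TUB1, TUB6 and TUA6 passed in 8 of 8 alternatives with all arrays, and TUB7 in 4 of 8, missing with median centring (adjusted p 0.0553), the replicate block (0.0777), spike-in centring (0.0863) and the seed storage covariate (0.113). With 1 array left out TUB1 and TUB6 passed in 6 of 6, TUA6 in 3 (not when any 1 flight array was left out) and TUB7 in 1 (without ground replicate 2). TUB1 stood at 7.29 ± 0.19 in flight and 4.71 ± 0.53 on the ground (log2, SD, n = 3). With the p-values adjusted over the list alone, 6 members were higher. The measured actin genes of the list, named after their values were seen, were not called in limma. ACT11 (AT3G12110) had a log2 change of 0.43 (adjusted p 0.371) and ACT12 (AT3G46520) one of -0.09 (0.773), with group means below the array medians. The list's other actin genes were not among the 10 measured, so the list cannot tell whether actin transcripts changed. Some actin control probe sets, given further below, were higher on all 3 flight arrays. With an estimated correlation the list had an adjusted p of 0.318. Class III peroxidases, enzymes that act in the wall, rose as a list (30 measured, adjusted p 0.00432), with 5 members higher and 0 lower, 5 also when adjusted over the list alone, and a median of 0.21. That median was 0.12 without ground replicate 4, 0.13 without flight replicate 3, 0.32 without ground replicate 3, 0.053 after spike-in centring, 0.38 on flight replicates 2 and 3 against ground replicate 2 and 1.10 once dim probe sets were left out. AT4G30170 rose by 2.41, AT4G11290 by 2.33 and AT2G22420 by 1.89, while Prx37 (AT4G08770) had a log2 change of 2.49 with an adjusted p of 0.184. The other called members, named after their values were seen, were PRXR1 (AT4G21960, 1.60) and AT5G66390 (1.25), which both missed the threshold with the seed storage covariate and when any 1 flight array was left out, as AT4G11290 did without flight replicate 2 and without flight replicate 3. With an estimated correlation the list had an adjusted p of 0.348.

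The plastid-encoded genes rose as a list (69 measured, camera adjusted p 8.38e-06), with a median of 0.48, although 0 of them passed the test singly, also when adjusted over the list alone. The largest differences were 1.52 in psbM (adjusted p 0.0948), 1.26 in ndhJ (0.174), 1.25 in psaJ (0.167) and 1.21 in rps16 (0.0853). With an estimated correlation the list had an adjusted p of 0.553, and without ground replicate 4 its median was 0.10 with a camera adjusted p of 0.298 (8.47e-12 to 0.553 over the alternatives). The median was 0.29 with the seed storage covariate (adjusted p 0.00750) and 0.21 on flight replicates 2 and 3 against ground replicate 2 (0.0300).

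The mitochondrion-encoded, heat shock and abscisic acid and dehydration lists shifted down with a preset correlation. The mitochondrion-encoded genes fell (11 measured, camera adjusted p 1.96e-05), with 2 members lower and 0 higher, 8 lower when adjusted over the list alone, and a median of -0.76. The respiratory complex I genes nad5 and nad4 changed by -1.12 (SE 0.15) and -1.07 (SE 0.24), while nad9 had a log2 change of -1.27 (adjusted p 0.0512) and nad4L one of -0.83 (0.0943). nad4 missed the threshold with quantile normalization (adjusted p 0.0623) and the seed storage covariate (0.0943) and passed in 1 of 6 alternatives with 1 array left out, that without ground replicate 4, while nad5 missed without flight replicate 3 and without flight replicate 4. The estimated correlation gave an adjusted p of 0.431. Heat shock genes fell as a list (8 measured, adjusted p 0.00194), with 3 members lower and 0 higher, 4 lower when adjusted over the list alone, and a median of -0.68. These were the small heat shock protein genes AT1G54050 (-3.36), AT1G53540 (-2.63) and AT5G51440 (-0.77), and AT1G52560 had a change of -1.05 with an adjusted p of 0.105. AT5G51440 missed the threshold with the trended prior (adjusted p 0.0877), the replicate block (0.0558), spike-in centring (0.0659), the seed storage covariate (0.0830) and any 1 array left out. AT1G54050 missed with the seed storage covariate (0.0668) and passed in 2 of 6 alternatives with 1 array left out, those without ground replicate 2 or 4, and AT1G53540 in 1 of 6, that without ground replicate 2. AT1G53540 read 7.98 and 7.91 in ground replicates 3 and 4, the arrays with high PAP85, and 5.78 in ground replicate 2. The adjusted p was 0.252 with an estimated correlation. The abscisic acid and dehydration list fell (4 measured, adjusted p 0.0152), with 2 members lower and 0 higher, 2 also when adjusted over the list alone, and a median of -0.77. These were the dehydrin genes LTI30, given above, and COR47 (AT1G20440), at -1.44 (SE 0.22), which missed the threshold when any 1 flight array was left out, while COR15A (AT2G42540) and COR15B (AT2G42530) differed by -0.11 (adjusted p 0.856) and -0.02 (adjusted p 0.970). The adjusted p was 0.318 with an estimated correlation, and 0.0776 in camera without ground replicate 2 (0.00148 to 0.318 over the alternatives). On flight replicates 2 and 3 against ground replicate 2 the median was -1.27 (adjusted p 0.00148).

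**Figure D2:**
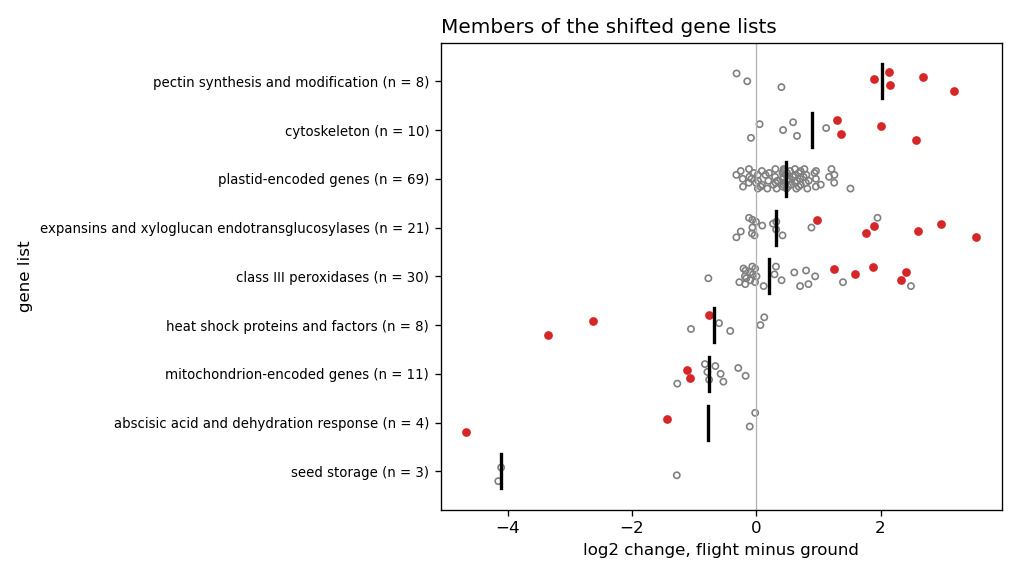
Log2 change of each measured member (flight minus ground, horizontal axis) of the 8 shifted gene lists and of the seed storage list. Filled points passed the adjusted p threshold in limma, open points did not, and the bar is the median of the list, from -4.11 in the seed storage list to 2.02 in the pectin list.

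The other 12 tested lists did not pass, with camera adjusted p from 0.0835 to 0.909. Their medians were 0.59 for the nuclear-encoded photosynthesis genes (7 measured), 0.23 for auxin response and transport (8, fry adjusted p 0.0410), -0.57 for dark and sugar starvation (6), -0.17 for flavonoid synthesis (5), -0.21 for jasmonate (4) and -0.13 for epidermis, stomata and meristem markers (4), with 0 members called in each over all probe sets. When adjusted over the list alone, 2 photosynthesis genes and 1 auxin gene were higher and 0 members of the other 4 lists passed. Of 10 hypoxia genes, with a median of 0.0053, AT4G10270 rose by 2.01 and AT3G27220 by 1.06 while AT3G10020 changed by -1.88, and adjusted over the list alone 4 were higher and 2 lower. STZ (AT1G27730), a zinc finger transcription factor gene, was the 1 called member of 9 in the touch, calcium and wound list (-1.76, list median -0.07), and 2 members were lower when adjusted over the list alone. BZIP60 (AT1G42990), a transcription factor of the unfolded protein response, changed by -1.03 in a list of 3 with a median of 0.61. The DNA replication gene PRL (AT4G02060) rose by 1.48 in the cell cycle list (3 measured, median 0.63), and GSTU20 (AT1G78370) rose by 1.91 among 3 glutathione S-transferases (median 0.04). Adjusting over the list alone left 1 called member in each of these last 3 lists. These single genes were named after their values were seen. STZ and AT3G10020 passed in 8 of 8 alternatives with all arrays and in 6 of 6 with 1 left out, GSTU20 and AT3G27220 in 7 of 8 and 4 of 6, AT4G10270 and BZIP60 in 6 of 8 and 2 of 6, and PRL in 5 of 7 and 2 of 6.

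The first principal component held 58.5% of the variance and placed the flight arrays between -57.14 and -30.04 and the ground arrays between 6.40 and 74.76. The second held 19.1% and set ground replicate 2, at -63.19, apart from the other 5 arrays. On the first component that array lay at 6.40, ground replicates 3 and 4 at 55.92 and 74.76, and flight replicate 4 at -30.04. Ground replicate 2 correlated at 0.943 to 0.950 with the flight arrays and at 0.942 and 0.936 with ground replicates 3 and 4. The ground arrays thus did not form 1 close cluster. The difference between the 3′ and 5′ probe sets of control transcripts, which follows how far labelled RNA reached toward the 5′ end, was compared for 6 pairs. One pair, an actin control, had groups that did not overlap, with 4.49 ± 0.23 in flight and 3.89 ± 0.20 on the ground (log2, SD, n = 3; two-sided exact permutation p 0.1, the smallest that 3 against 3 arrays allow, adjusted p 0.6). The other 5 pairs overlapped, with group differences from -0.07 to 0.36 and exact p from 0.3 to 0.9.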

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

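Levels of the plant control probe sets, which were left out of the comparison, were higher on all 3 flight arrays than on all 3 ground arrays for 7 of 18 such probe sets. Chance gives 5% for each in this direction, and the opposite direction was not counted. Over all probe sets tested, 26.0% had groups that did not overlap in either direction. The 18 are not independent, and all 7 belong to actin or GAPDH. For actin the flight minus ground differences (log2) were 0.53 (3′ end) and 0.20 (middle) in the first probe design and 0.67 (3′ end) and 0.37 (middle) in the second. For GAPDH they were 0.59 (3′ end) and 0.45 (middle) in the first design and 0.69 (5′ end) in the second. Each had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. All 7 differences stayed above 0 after median centring (smallest 0.14, 5 of 7 still without overlap) and after centring on spike-ins (smallest 0.05, 4 of 7 without overlap).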

How the results depend on the processing

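Alternatives marked here as added were chosen after seeing the data. The higher and lower counts stayed within 1.5 times of 939 and 413 under quantile normalization, median centring, the dim filter, the trended prior, array weights and a log2 change of at least 1 with either p. At an adjusted p under 0.10 they were 1532 and 750. The plain equal-variance test called 0 and 0 after adjustment, with 3805 probe sets at an unadjusted p under 0.05 against 4780 in limma. With 1 array left out the higher count ran from 188 to 1124 and the lower from 83 to 782; fewer arrays give less power, but the rise without ground replicate 2 has no tested cause. Added settings gave 470 higher (spike-in centring), 415 (seed storage covariate) and 346 (flight replicates 2 and 3 against ground replicate 2, where the lone ground array is assumed to vary like the others); the cause was not tested beyond the fewer residual degrees of freedom of the last 2. Spike-in centring moved the median of all probe sets by -0.15 and the share of higher calls from 69.5% to 56.4%. Ground replicate 4 decides this: the spike-in mean, flight minus ground, was 0.15 with it and -0.042 without it. With the replicate block, 733 were higher and 373 lower; deviations of same-numbered arrays correlated at 0.202, -0.026 and 0.271, and flight replicate 3 correlated best with ground replicate 2 (0.22), so the numbers were not taken to pair the arrays.

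Of 53 genes named by the rule, 30 to 51 kept their direction and their side of the threshold under each setting, the fewest without flight replicate 3, where 23 fell short of it. The number of shifted lists was 7 to 9 under every setting but 1: camera with an estimated correlation passed 0 of 20, with 2 at an unadjusted p under 0.05 and 7 passing in fry, which passed the auxin list but not the mitochondrion- and plastid-encoded lists. The dehydration list did not pass without ground replicate 2, nor the plastid list without ground replicate 4. Without detection calls, changes near the array medians have no known signal over background. COR15B turned to 0.013 with quantile normalization. With 1 array left out COR15B ran from -0.12 to 0.082 (without ground replicate 3) and COR15A from -0.25 to 0.16 (without ground replicate 2); the cause was not tested. With the seed covariate PAP85 turned to 0.52 and OLEO3 to 0.50, and on the 3 arrays with low seed storage values the seed storage list turned to 0.052, PAP85 to 0.052 and OLEO3 to 1.22, as those settings remove the seed signal by construction.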

Other observations

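The gene families by symbol stem, the comparisons with ground replicate 2, the abscisic acid list as an explanation, the spike-in test of the higher probe sets and those with the seed storage covariate were tests chosen only after the results were seen. For the LEA genes, the bounds of the seed storage and spike-in tests were written before their outcomes. The seed storage list was fixed beforehand, but spike-in centring itself was an alternative added after the data were seen. Of 47 families sharing a symbol stem with at least 5 measured genes, 6 passed camera with a preset correlation, and 3 of these are not described above. With an estimated correlation none of the 47 passed (adjusted p 0.814 for each of these 3). The RALFL genes, which encode small secreted peptides of the RALF type, had 2 of 11 members higher and a median log2 change of 0.75 (camera adjusted p 0.00801): RALFL34 (AT5G67070) rose by 2.50 and RALFL31 (AT4G13950) by 1.49. Their camera adjusted p was 0.0521 without ground replicate 4 and 0.101 with the seed storage covariate (8.26e-05 to 0.335 over the 15 alternatives run with the preset correlation). Of 22 TBL genes, whose family includes wall polysaccharide acetyltransferases, 4 rose, TBL36 (AT3G54260) by 2.58, TBL38 (AT1G29050) by 1.93, TBL37 (AT2G34070) by 1.93 and TBL39 (AT2G42570) by 1.65; the family median, 0.14 (camera adjusted p 0.0364), turned to -0.02 after spike-in centring and -0.01 with the seed covariate, and the adjusted p was 0.152 without flight replicate 2 and 0.168 without ground replicate 4 (0.00234 to 0.254 over the same 15).

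The ccb genes, mitochondrial genes of cytochrome c maturation that kept the annotation's symbols and so stood outside the mitochondrion-encoded list, were tested as a family, and 3 of 5 members passed singly. ccb452 changed by -1.18 (SE 0.18), ccb206 by -1.08 (SE 0.21) and ccb203 by -1.04 (SE 0.16). ccb382 had a log2 change of -0.36 (adjusted p 0.502). The stem also takes in the nuclear gene CCB3 (AT5G36120), at -0.30 (adjusted p 0.447), and the 5 genes had a median of -1.04 (camera adjusted p 0.00225). Over 14 alternatives run with the preset correlation its camera adjusted p ran from 0.000811 to 0.0176, and it had too few genes once dim probe sets were left out.

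The lower flight levels of LEA18, AtLEA4-1, LEA4-5 and M10 may come from ungerminated or dry seed in the ground samples, from array scaling, or from an abscisic acid or dehydration response. The 12 named lower genes, these 4 among them, had a median of -5.02 after spike-in centring, against -4.87 before. Centring shifts the difference of every probe set by the same -0.15, so this outcome followed from the spike-in means. It argues only against a constant offset per array, as the spike-ins read it, being as large as these falls. Scaling that differs between probe sets was not tested. Seed material remains open as part or all of the difference for ground replicates 3 and 4. A difference in growth stage between the groups also stays open and was not tested. The seed storage genes, a set chosen beforehand, had a median of -4.11 with 3 of 3 lower, although none passed singly. With their mean as a covariate the 12 largest falls chosen without ground replicate 2 moved from a median of -4.70 to -1.22. The 12 named lower genes kept a median of -3.83 with that covariate and 9 of them their calls. Their choice required ground replicate 2, low in seed storage transcripts, to lie above flight. A difference left after the covariate was thus favoured by the choice, so it does not weigh against seed as the whole cause. For the abscisic acid list the median was -0.77, between the bounds set for and against; it lay past the bound for, at -1.05 (adjusted p 0.00365) with the seed covariate and -1.27 (0.00148) on flight replicates 2 and 3 against ground replicate 2 (0.00148 to 0.318 over the alternatives), but LTI30, itself 1 of the 12, and COR47 carry this while COR15A (-0.44 and -0.61) and COR15B (-0.021 and -0.035) did not pass in either, so that response cannot be told apart from the rest here.

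On ground replicate 2 the 12 named lower genes lay above flight, but their choice required this. The 12 largest falls chosen by the same rule without that array, of which 2 are among the named ones, lay above the mean of flight replicates 2 and 3 by a median of 0.40 there, and 4 of them by at least 1 (LEA18 by 6.36, AT3G15670 by 5.20, AT3G17520 by 2.79 and AT3G53040 by 1.69). The seed storage genes differed by a median of -0.052, which argues against ungerminated seed in that sample as the source of these 4 values. A difference in the water or hormone state of the ground seedlings stays open: the abscisic acid list had a median of -1.27 in flight replicates 2 and 3 against that 1 array, carried by LTI30 and COR47.

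The 939 probe sets higher in flight could reflect seed RNA diluting seedling RNA on the ground arrays, or scaling. With the seed storage mean as a covariate they had a median log2 change of 1.17 (quartiles 0.89 and 1.62), against 1.26 without it. Of them 377 stayed called, in a fit with 1 residual degree of freedom fewer. Each of the 939 had ground replicate 2, low in seed storage transcripts, below every flight array. A difference left after the covariate was thus favoured by the choice, so it does not weigh against seed RNA as the whole cause. The 1124 probe sets called higher without ground replicate 2 had a median of 0.996 with the covariate (quartiles 0.70 and 1.49), against 1.14 without it. Their choice did not use that array, where they differed from the flight mean by a median of -0.90. For these probe sets this argues against seed RNA as the whole cause, resting on 1 ground array. After spike-in centring, the same shift of -0.15 for every probe set, the median was 1.10 (quartiles 0.80 and 1.57), and 434 stayed called. This argues only against a constant offset per array, as the spike-ins read it, as the whole cause. Ground replicate 4 decides that centring. Flight itself, and any difference in growth stage between the groups, stay open as biological explanations and are untested.

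The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1352 probe sets and the highest other split 5, and the real split shifted 8 lists and the highest other split 5. In each case 1 of the 10 splits, the real one, reached the real value. The split of flight replicate 2 with ground replicates 3 and 4 called 0 probe sets but passed 5 lists. The remaining mixed splits passed 0 to 4 lists. Camera with the preset correlation can thus pass lists in mixed groupings of these arrays.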
